A study of Homo sapiens with 24 samples.

How the data were processed

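The 24 arrays measured RNA from cultured human lung microvascular endothelial cells with and without LPS after 4, 8 and 24 h, 4 arrays in each of 6 groups, on Affymetrix HG-U133 Plus 2 arrays of 54675 probe sets. The deposited values are signal intensity per probe set on a linear scale, and MAS5 is named in the submitters' processing notes. The values of each array, without the highest and lowest 2%, averaged 100, so the authors scaled each array to a common trimmed mean. Nothing in the values showed a further normalization between arrays: medians ranged from 14.3 to 18.5 (0.37 on the log2 scale) and the highest signals from 7284 to 15891. The software version, background settings, detection calls, and whether replicates were separate cultures are not given in the sources used here, so p-values measure the spread between these samples alone.

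Probe sets were assigned to genes with the platform's annotation, symbols being updated by Entrez ID for 41043 probe sets and kept for 54. Of the probe sets 41097 had 1 gene symbol, 1801 several and 11777 none, 62 of these being control probe sets. Each of 19775 genes was represented by the probe set with the highest mean over the 24 arrays among those with 1 symbol. Genes entered where that probe set exceeded 16.006, the median of all values, in at least 4 arrays, which left 14404. Because the array medians lay within 0.5 log2 of each other, values were used as deposited, as log2(signal + 16). Genomic positions were not used here.

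A linear model with a mean for each of the 6 groups was fitted to the 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes, 2-sided, prior degrees of freedom 4.22), and Benjamini-Hochberg adjusted p under 0.05 over the 14404 genes was called. The contrasts were LPS against the control of the same time, the 3 differences of that change between times, and control 8 h and control 24 h against control 4 h. The 23 gene lists held 631 entries, of which 596 had a probe set with 1 symbol and 557 were measured. They were tested with camera (preset correlation 0.01), adjusted over the 69 tests of 23 lists and 3 LPS contrasts, and the 3 differences between times were adjusted in the same way. Camera compares a list with the other genes, so a shift shared by all genes leaves it unchanged.

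The groups, comparisons, lists, named genes and most alternatives were fixed before the data were examined. Genes were named by rule: for each LPS comparison the 6 highest and 6 lowest called changes with no overlap between LPS and control arrays, a fixed panel of 13 genes, and up to 3 called members with the largest change in each list described; for each difference between times, and for control 24 h against 4 h, the 4 highest and 4 lowest called changes. Further members of counts of 5 or fewer, members of a list that did not pass, and other members named to show both directions were chosen after their values were seen. XIST and Y-linked genes are not reported. By the rule 137 genes were named in 223 results, and 87 further results were named after their values were seen, in all 310 of 186 genes, all run under the alternatives below.

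The array batch was found in the data and chosen after seeing them. The mean log2 signal of the 18 spike-in probe sets was divided into 2 classes by the division with the least spread within classes, at 8.59, which gave 10 low and 14 high arrays. A first rule, the largest gap, had set apart 1 array alone, and the rule was changed knowing that other technical probe sets and the highest signal divided the arrays 10 to 14. The spike-in means form a range rather than separate clusters, since the gap at the division was 0.45 log2 and the largest gap elsewhere 0.48, but the highest signal was at most 9811 on low and at least 11136 on high arrays. The batch as a covariate, the high arrays alone, the low arrays alone, and camera with the batch or on the differences between times were added as alternatives after seeing the data.

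The alternatives set beforehand were shifting arrays to the same median, quantile normalization, pseudocounts of 1 and 64, no filter or a filter at the 75th percentile (85.4), the mean of all probe sets of a gene, leaving out probe sets ending in _x_at, every probe set on its own, the arrays compared alone, a trend with a robust prior, array quality weights, a replicate block, leaving out each array, and for lists fry, an estimated correlation, quantile normalization and a pseudocount of 64. The fit was tested on data simulated at observed means and spreads, 200 of 14404 genes being changed in LPS 4 h. It recovered 19.4%, 61.2% and 87.9% of genes changed by 0.5, 1 and 2 log2 (n = 67, 67 and 66). Of its 120 calls 8 were false (6.67%), and 0 genes were called at 8 h, where none changed. Camera called a list of 25 genes moved by 0.5 and 0 of 40 unchanged lists, correlated genes being untested.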

Results

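Transcript levels were measured in cultured human lung microvascular endothelial cells. The cells were left untreated or given lipopolysaccharide (LPS), the outer membrane glycolipid of Gram-negative bacteria that Toll-like receptor 4 recognises, at 10 ng with no volume stated. Cells were collected after 4, 8 and 24 h, with an untreated control at each time. Each of the 6 groups held 4 arrays of 54675 probe sets. Array medians lay between 14.3 and 18.5 signal units, and arrays of a group correlated with each other at r between 0.971 and 0.988 across probe sets, which are not independent replicates. Genes are said to have risen or fallen where limma's adjusted p was under 0.05, changes are on the log2 scale with their SE, and n = 4 arrays per group throughout.

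The arrays also split on a technical measure that no label names. The 18 spike-in probe sets read control transcripts, bacterial bio and bacteriophage cre. Their geometric mean signal was 149 to 329 on 10 arrays, called low below, and 451 to 958 on the other 14, called high. Low arrays made up 3 of 4 in control 4 h and in control 24 h, and 1 of 4 in control 8 h and in each LPS group. The split therefore went partly with LPS at 4 h and at 24 h and was balanced at 8 h. With the split as a batch term, 481 of 14404 genes differed between low and high arrays, 382 of them lower on the low arrays. The 145 brightest genes had a median batch difference of -0.59 and median LPS changes of 0.31, 0.00 and 0.20 at 4, 8 and 24 h. Values with the batch term, and from the high or low arrays alone, stand beside the counts and the median log2 changes of lists below (batch term, high, low). Within the high or low arrays, 3 arrays are compared with 3 for LPS at 8 h (high) and for control 24 h against 4 h (low), and every other comparison has a group of 1 array, assumed to vary like the other groups, so that those counts are limited by the design.

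**Figure D1:**
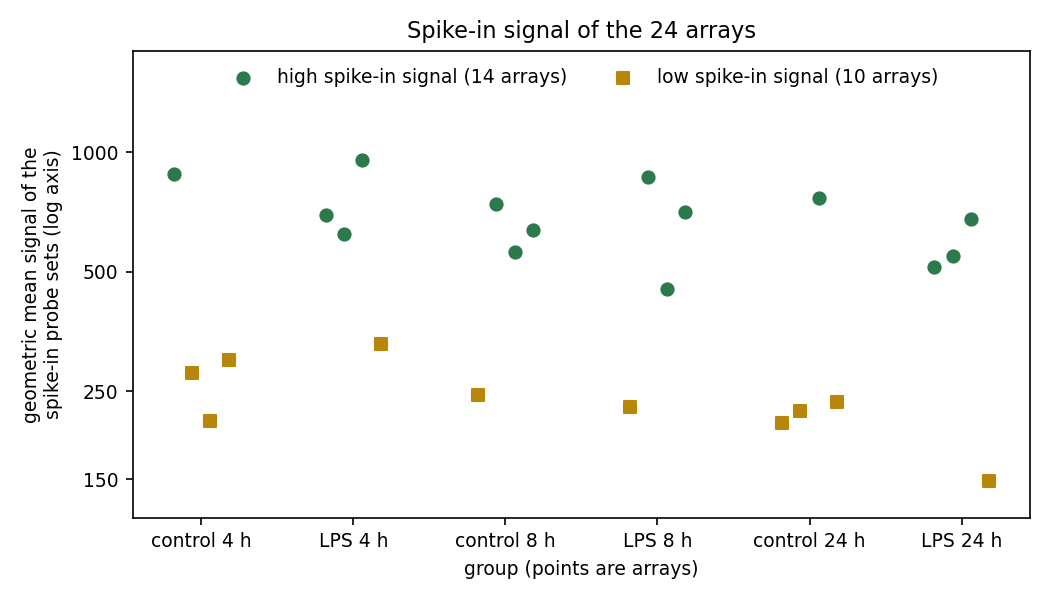
Geometric mean signal (log axis) of the 18 spike-in probe sets on each of the 24 arrays, by group, where points are arrays. Of the 10 low arrays (squares) 3 were in control 4 h and 3 in control 24 h, and the 14 high arrays (circles) lay above them.

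After 4 h of LPS, genes for leukocyte recruitment were among those that rose most. SELE, the endothelial selectin on which leukocytes roll, rose from 62.1 ± 9.67 to 8286 ± 709 (mean signal ± SD, n = 4), a change of 6.74 ± 0.34 (SE, adjusted p = 1.03e-12). The neutrophil chemokines CXCL3 and CXCL2 rose by 7.28 ± 0.17 and 5.91 ± 0.23, the granulocyte growth factor CSF3 by 6.68 ± 0.22, the cytokine IL6 by 6.42 ± 0.21 and the chemokine CCL20 by 5.40 ± 0.25. CXCL2, a close paralog of CXCL3, was read from a probe set ending in _x_at, and its 2 other probe sets gave 0.54 and 2.71. A group mean lay under the filter value of 16.006 for CSF3, IL6, ELF3, MAP3K8, PDK4, SOCS1 and TNIP3, so that their values depend on the pseudocount: with 1 and 64 in place of 16 CSF3 was 8.73 and 4.97 and IL6 was 7.68 and 5.02. VCAM1 and ICAM1, ligands of leukocyte integrins, rose by 5.33 ± 0.31 and 3.67 ± 0.16, and F3, the tissue factor that starts coagulation, by 4.93 ± 0.19. GJA4, a gap junction protein of arterial endothelium, fell by 2.37 ± 0.32 from 467 ± 33.1 to 79.6 ± 24.9 (adjusted p = 1.65e-05). The next lowest changes were those of PRR15 (-2.06), RUNX1T1 (-1.82), DTX4 (-1.79), FAM124B (-1.74) and PDK4 (-1.70), a kinase that restrains pyruvate oxidation.

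Of the panel named at every time, CXCL8, the main neutrophil chemokine of endothelium, rose by 4.00 ± 0.30, NFKBIA, the inhibitor that retains NF-kB in the cytoplasm, by 2.53 ± 0.15 and the monocyte chemokine CCL2 by 2.18 ± 0.19. SOD2, the mitochondrial superoxide dismutase, rose by 1.89 ± 0.38. The vascular cadherin CDH5 (0.23 ± 0.12), the endothelial nitric oxide synthase NOS3 (-0.30 ± 0.23), the anticoagulant receptor THBD (0.05 ± 0.10) and the LPS receptor TLR4 (-0.51 ± 0.20) did not pass. With all probe sets of a gene averaged, the NOS3 value was 0.012.

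Among NF-kB subunits, inhibitors and feedback targets, 18 rose, 0 fell and 2 did not pass among 20 (adjusted over the list alone, 18 and 0). Examples were the inducible factor TNFAIP2 (4.55), the ubiquitin-editing inhibitor TNFAIP3 (3.5) and the related inhibitor TNIP3 (3.44), while NFKBIB (0.22) and RELA (0.30) did not pass. The NF-kB median was 1.44 (batch term 1.41, high 1.36, low 1.52). For NF-kB genes camera gave adjusted p = 3.77e-52, or 8.72e-06 with an estimated correlation. Of the cytokines and chemokines, 23 rose, 2 fell and 7 did not pass among 32 (adjusted over the list alone, 23 and 2), and those that fell were the lymphoid growth factor IL7 (-1.64) and the chemokine CXCL12 (-0.69). The cytokine median was 1.92 (batch term 1.79, high 1.73, low 1.68). For cytokine genes camera gave adjusted p = 5.42e-48, or 8.72e-06 with an estimated correlation. Of the leukocyte adhesion molecules, 3 rose, 1 fell and 19 did not pass among 23 (adjusted over the list alone, 3 and 1): SELE, VCAM1 and ICAM1 rose and ICAM3 (-0.51) fell. The adhesion median was 0.14 (batch term 0.05, high 0.02, low 0.04). For adhesion genes camera gave adjusted p = 7.66e-05, lost with an estimated correlation, adjusted p = 0.0808.

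Immediate early genes and signalling feedback moved in both directions: 12 rose, 3 fell and 9 did not pass among 24 (adjusted over the list alone, 15 and 3). The stress-induced transcription factor ATF3 (2.85) and the cytokine signalling inhibitors SOCS3 (2.90) and SOCS1 (2.65) rose, and DUSP4 (-0.99), SOCS2 (-0.80) and SPRY2 (-0.61) fell. The immediate early median was 0.46 (batch term 0.42, high 0.43, low 0.57). For immediate early genes camera gave adjusted p = 2.68e-14, or 4.70e-06 with an estimated correlation. Of the antigen processing and interferon-gamma-type genes, 9 rose, 0 fell and 19 did not pass among 28 (adjusted over the list alone, 10 and 0), among them the transcription factors IRF1 (2.95) and IRF8 (2.72) and the GTPase GBP1 (2.79). The antigen processing median was 0.25 (batch term 0.12, high 0.05, low 0.23). For antigen processing genes camera gave adjusted p = 3.30e-12, or 0.00691 with an estimated correlation. Of the type I interferon-stimulated genes, 8 rose, 1 fell and 29 did not pass among 38 (adjusted over the list alone, 9 and 1). The RNA sensor IFIH1 (1.07) and SAMD9L (0.93) and ISG20 (0.86) rose and OAS1 (-0.60) fell. The interferon median was 0.10 (batch term 0.12, high -0.01, low 0.20). For interferon genes camera gave adjusted p = 7.66e-05, or 0.00434 with an estimated correlation. Among genes of Toll-like receptor signalling, 4 rose, 0 fell and 26 did not pass among 30 (adjusted over the list alone, 5 and 0), the kinases MAP3K8 (4.85) and IRAK2 (2.35), the receptor TLR2 (1.38) and the adaptor TAB2 (0.77) having risen. The Toll-like receptor median was 0.10 (batch term 0.10, high 0.09, low 0.12). For Toll-like receptor genes camera gave adjusted p = 3.29e-04, or 0.00365 with an estimated correlation.

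Of the coagulation and fibrinolysis genes, 3 rose, 1 fell and 16 did not pass among 20 (adjusted over the list alone, 6 and 1), F3 and the protease inhibitors SERPINE2 (0.67) and TFPI2 (0.51) having risen and the protein C receptor PROCR (-0.31) having fallen. The coagulation median was 0.09 (batch term -0.02, high 0.10, low 0.06). For coagulation genes camera gave adjusted p = 6.33e-04, or 0.0171 with an estimated correlation. Vascular barrier and tone regulators included the prostaglandin synthase PTGS2 (3.34), the receptor S1PR1 (0.63), the lymphangiogenic factor VEGFC (0.61) and ROCK2 (0.40), which rose, and the receptor KDR (-0.59), which fell: 4 rose, 1 fell and 31 did not pass among 36 (adjusted over the list alone, 6 and 1). The barrier median was 0.06 (batch term 0.03, high -0.03, low 0.10). For barrier genes camera gave adjusted p = 0.0103, or 0.0354 with an estimated correlation, lost with the batch term as well, adjusted p = 0.0734. After quantile normalization the barrier call was lost (adjusted p = 0.0894). Of the matrix genes and proteases, 6 rose, 0 fell and 30 did not pass among 36 (adjusted over the list alone, 6 and 0), with MMP10 (3.48) and ADAMTS9 (1.63) and the growth factor TGFB2 (1.56) the most changed. The matrix median was 0.19 (batch term -0.01, high -0.14, low 0.15). For matrix genes camera gave adjusted p = 9.54e-06, lost with an estimated correlation, adjusted p = 0.0628, passing with the batch term as well, adjusted p = 0.0470. Of the DNA replication genes, 0 rose, 2 fell and 29 did not pass among 31 (adjusted over the list alone, 0 and 6), the helicase subunit MCM6 (-0.45) and the clamp loader RFC4 (-0.41) having fallen. The replication median was -0.29 (batch term -0.28, high -0.21, low -0.30). For replication genes camera gave adjusted p = 0.00780, lost with an estimated correlation, adjusted p = 0.481. Of the unfolded protein response genes, 5 rose, 1 fell and 20 did not pass among 26 (adjusted over the list alone, 5 and 1), with CEBPB (1.25) and XBP1 (0.81) higher and the growth inhibitor DDIT4 (-0.79) lower, the other XBP1 probe set moving the opposite way. The unfolded protein median was 0.01 (batch term -0.02, high -0.04, low 0.04). For unfolded protein genes camera gave adjusted p = 0.0134, lost with an estimated correlation, adjusted p = 0.193. With the batch term the unfolded protein call was lost (adjusted p = 0.0710).

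Endothelial transcription factors and surface markers went both ways: 6 rose, 11 fell and 17 did not pass among 34 (adjusted over the list alone, 7 and 15). The flow-responsive factor KLF4 (2.53) and the Notch target HEY1 (2.19) rose and the vascular factor SOX18 (-1.61) fell. The endothelial median was -0.23 (batch term -0.29, high -0.41, low -0.29). For endothelial genes camera gave adjusted p = 0.150, which did not pass. With the batch term this list passed as lower (adjusted p = 0.0473), a call lost with an estimated correlation (adjusted p = 0.154). The other lists did not pass camera's test at 4 h. Of the junction proteins 1 of 21 rose and 2 fell (adjusted over the list alone 1 and 3, camera adjusted p = 0.902), with CLDN1 (1.31) higher and GJA4 (-2.37) and MARVELD2 (-0.57) lower. Of the lymphatic markers 1 of 11 rose and 3 fell (adjusted over the list alone 1 and 3, camera adjusted p = 0.316), with PDPN (0.56) higher and PROX1 (-0.76), MAF (-0.69) and FLT4 (-0.40) lower, 2 of 3 other MAF and 1 of 2 other FLT4 probe sets having the same sign. Of the mitotic genes 0 of 32 rose and 0 fell (adjusted over the list alone 0 and 0, 0 and 0 at unadjusted p under 0.05, camera adjusted p = 0.550). Of the apoptosis regulators 4 of 31 rose and 4 fell (adjusted over the list alone 5 and 4, camera adjusted p = 0.137), the kinase RIPK2 (2.71), PMAIP1 (1.17), TNFRSF10B (0.80) and MCL1 (0.38) being higher and BCL2L1 (-0.73), GADD45A (-0.55), CASP8 (-0.54) and GADD45B (-0.47) lower. Of the oxidative stress genes 2 of 29 rose and 1 fell (adjusted over the list alone 2 and 1, camera adjusted p = 0.0562): SOD2, the cystine transporter SLC7A11 (0.89) and the oxidase NOX4 (-0.36). Of the cholesterol genes 1 of 21 rose and 0 fell (adjusted over the list alone 1 and 0, camera adjusted p = 0.804), the riser being INSIG1 (0.70).

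Of the markers of other cell types at 4 h, among leukocyte markers 0 of 8 rose and 0 fell (adjusted over the list alone 0 and 0, 0 and 1 at unadjusted p under 0.05, camera adjusted p = 0.818), among fibroblast markers 0 of 11 rose and 0 fell (adjusted over the list alone 0 and 0, 1 and 1 at unadjusted p under 0.05, camera adjusted p = 0.351), among smooth muscle markers 0 of 9 rose and 0 fell (adjusted over the list alone 0 and 0, 0 and 0 at unadjusted p under 0.05, camera adjusted p = 0.804) and among epithelial markers 1 of 6 rose and 0 fell (adjusted over the list alone 1 and 0, camera adjusted p = 0.337). The epithelial riser was the transcription factor ELF3 (1.04). The median, mean and test differed in sign for the cholesterol, apoptosis and smooth muscle lists.

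Limma called 1184 of 14404 genes at 4 h, 524 higher and 660 lower, and 252 of them changed at least 2-fold, 198 higher and 54 lower. Of the called genes 1111 had all 4 LPS arrays on the same side of all 4 control arrays, and 16.1% of the genes tested did so, against 2.86% by chance. With the batch term 1050 genes were called, 970 of the 1184 among them, while the high arrays alone (3 LPS arrays against 1 control) gave 203 and the low arrays alone (1 against 3) 303. The split depended on scaling: it was 672 higher and 356 lower with each array shifted to the same median, and 597 and 462 after quantile normalization. Of the 84 called genes named for 4 h, here or among the observations, 71 were still called with the batch term, and the call was lost for BCL2L1, CXCL12, FLT4, GADD45A, GADD45B, MAF, MARVELD2, MCM6, NOX4, PDPN, PROCR, RFC4 and S1PR1 (adjusted p = 0.0501 to 0.123). Leaving out 1 array ended these calls, except that of PDPN, and those of CASP8, ICAM3, MCL1 and PROX1 in 2 to 7 of the 8 fits each (adjusted p up to 0.176). Averaging all probe sets of a gene ended those of BCL2L1, CASP8, FLT4, MAF, MCM6, SERPINE2, SOCS2 and XBP1. High or low arrays differed from all arrays by over 1.5 times for KDR (-0.59, -0.35), MAF (-0.44, -0.52) and MCL1 (0.21, 0.53). Others were MCM6 (-0.20, -0.54), NOX4 (-0.20, -0.35), ROCK2 (0.24, 0.53), SERPINE2 (1.01, 0.67), SOCS2 (-0.5, -0.80) and SOD2 (2.49, 1.13).

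After 8 h of LPS SELE, VCAM1 and 4 chemokines had the highest changes, and the nitric oxide synthase gene was lower. SELE rose from 12.5 ± 8.71 to 2808 ± 1346, by 6.58 ± 0.34 (adjusted p = 3.14e-12), and VCAM1 from 22.7 ± 8.12 to 1698 ± 717, by 5.41 ± 0.31 (adjusted p = 1.42e-11). The chemokines CCL20, CXCL6, CXCL2 and CXCL3 rose by 5.38 ± 0.25, 5.33 ± 0.23, 5.03 ± 0.23 and 4.90 ± 0.17, the other CXCL2 probe sets giving 0.58 and 2.19. A group mean lay under the filter value of 16.006 for SELE, B3GALT2, COL3A1, DLL4, E2F1, F3, JAM2, MAP3K8 and SOCS1, so that their values depend on the pseudocount: with 1 and 64 in place of 16 SELE was 7.85 and 5.14, and JAM2 was not called with 1. NOS3, whose product makes the vasodilator nitric oxide, fell by 1.59 ± 0.23 from 161 ± 68.6 to 41.3 ± 14.3 (adjusted p = 3.96e-05), and THBD, the thrombin receptor that starts the protein C pathway, fell by 0.81 ± 0.10 (adjusted p = 4.27e-06). The lowest changes were those of the glucose transporter SLC2A12 (-2.97), B3GALT2 (-2.02), RUNX1T1 (-1.94), LIMCH1 (-1.92) and GASK1B (-1.89) and GJA4 (-1.88), 2 of 3 other LIMCH1 probe sets having the same sign.

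In the panel CXCL8 rose by 4.62 ± 0.30, ICAM1 by 4.01 ± 0.16, IL6 by 2.51 ± 0.21, F3 by 2.05 ± 0.19, NFKBIA by 2.04 ± 0.15 and CCL2 by 1.78 ± 0.19. SOD2 rose by 1.61 ± 0.38. CDH5 (-0.08 ± 0.12) and TLR4 (-0.59 ± 0.20, adjusted p = 0.0551) did not pass. CDH5 changed sign in 2 settings. TLR4 passed as lower with the batch term (adjusted p = 0.00888), with all probe sets averaged (0.00282), without probe sets ending in _x_at (0.00974), without LPS 8 h replicate 1 (0.0466) or control 8 h replicate 4 (0.0316) and in 4 other settings (0.0274 to 0.0492).

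**Figure D2:**
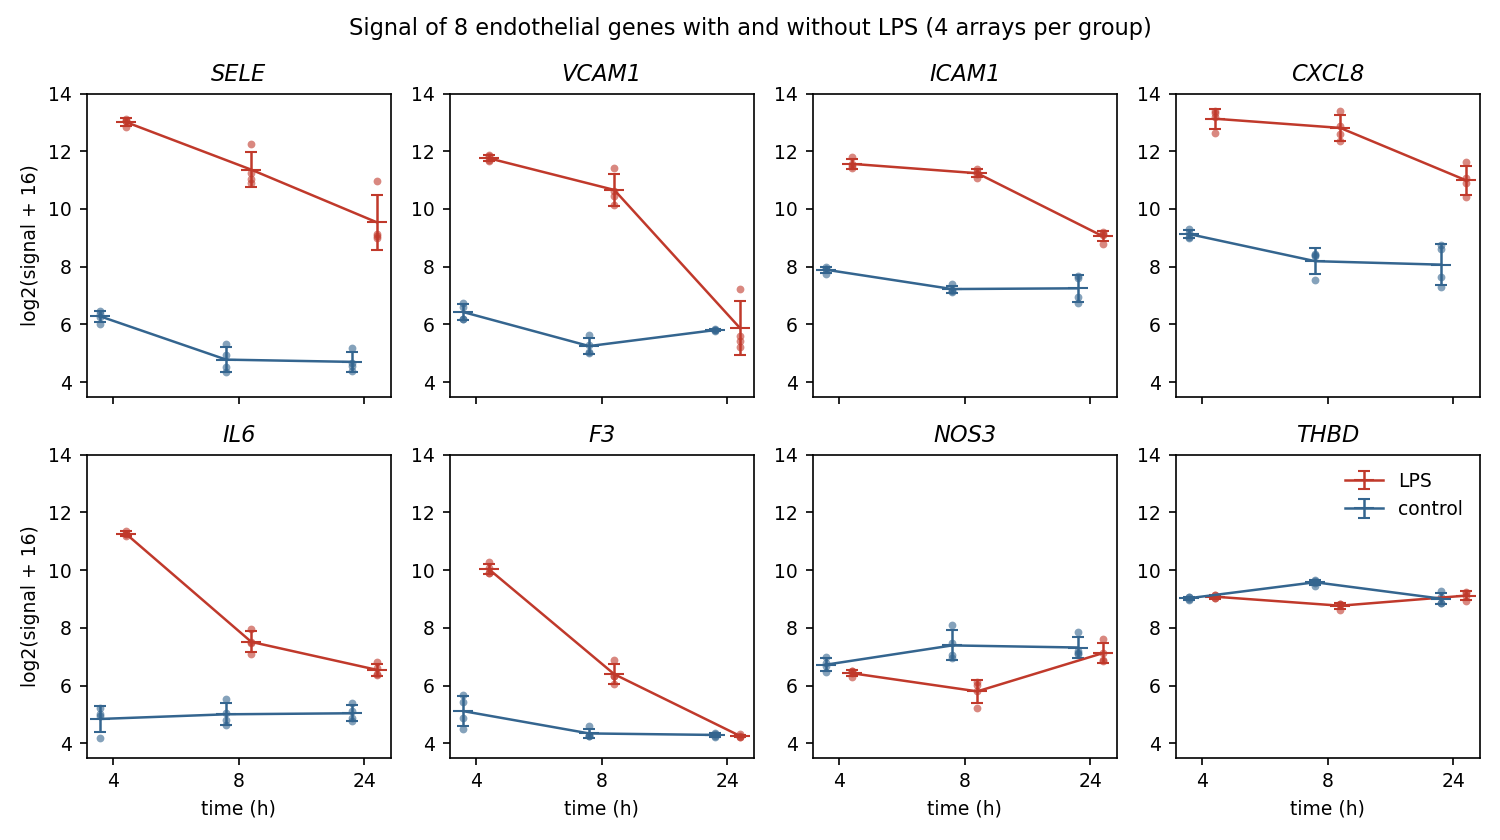
Signal, as log2(signal + 16), of 8 endothelial genes against time in hours with LPS (red) and without (blue), where points are arrays, dashes are group means and bars are SD (n = 4). SELE was higher with LPS at each time, VCAM1 and F3 rose at 4 and 8 h and did not pass at 24 h, and NOS3 and THBD fell at 8 h.

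Of the NF-kB genes, 17 rose, 0 fell and 3 did not pass among 20 (adjusted over the list alone, 18 and 0), with TNFAIP2 (3.57), TNFAIP3 (2.43) and TNIP1 (2.42) the most changed. The NF-kB median was 1.33 (batch term 1.33, high 1.37, low 1.36). For NF-kB genes camera gave adjusted p = 9.58e-38, or 3.45e-05 with an estimated correlation. Of the cytokines and chemokines, 24 rose, 1 fell and 7 did not pass among 32 (adjusted over the list alone, 24 and 1), IL7 (-1.44) having fallen. The cytokine median was 1.81 (batch term 1.81, high 1.87, low 1.69). For cytokine genes camera gave adjusted p = 9.58e-38, or 3.14e-05 with an estimated correlation. Of the antigen processing genes, 15 rose, 0 fell and 13 did not pass among 28 (adjusted over the list alone, 19 and 0). The interferon-inducible GTPases GBP1 (2.97), GBP3 (1.97) and GBP2 (1.88) were the most changed. The antigen processing median was 0.53 (batch term 0.53, high 0.55, low 0.66). For antigen processing genes camera gave adjusted p = 1.23e-18, or 0.00134 with an estimated correlation. Of the type I interferon-stimulated genes, 19 rose, 1 fell and 18 did not pass among 38 (adjusted over the list alone, 21 and 1), among them the exonuclease ISG20 (2.12), PARP14 (1.54) and the antiviral IFIT3 (1.43), while OAS1 (-0.69) fell. The interferon median was 0.58 (batch term 0.58, high 0.60, low 0.47). For interferon genes camera gave adjusted p = 3.31e-15, or 8.72e-06 with an estimated correlation.

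Of the DNA replication genes, 0 rose, 19 fell and 12 did not pass among 31 (adjusted over the list alone, 0 and 27). The replication initiator MCM10 (-1.13), the methylation maintenance factor UHRF1 (-0.97) and the transcription factor E2F1 (-0.85) fell most. The replication median was -0.60 (batch term -0.60, high -0.64, low -0.53). For replication genes camera gave adjusted p = 1.09e-13, lost with an estimated correlation, adjusted p = 0.0648. Of the mitotic genes 0 of 32 rose and 0 fell (adjusted over the list alone 0 and 0, 0 and 0 at unadjusted p under 0.05, camera adjusted p = 0.336). Endothelial factors and markers went both ways: 7 rose, 14 fell and 13 did not pass among 34 (adjusted over the list alone, 7 and 16), with SOX17 (-1.01) and the Notch ligand DLL4 (-0.98) lower and HEY1 (0.96) higher. The endothelial median was -0.30 (batch term -0.30, high -0.32, low -0.23). For endothelial genes camera gave adjusted p = 0.00558, lost with an estimated correlation, adjusted p = 0.0890, passing with the batch term as well, adjusted p = 0.0470. Of the lymphatic markers, 1 rose, 6 fell and 4 did not pass among 11 (adjusted over the list alone, 1 and 7): the lymphatic master regulator PROX1 (-1.15) and COLEC12 (-0.91) fell and the mucin PDPN (0.88) rose, 2 of 3 other PDPN probe sets having the same sign. The lymphatic median was -0.44 (batch term -0.44, high -0.49, low -0.28). For lymphatic genes camera gave adjusted p = 0.00590, lost with an estimated correlation, adjusted p = 0.188.

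Of the leukocyte adhesion molecules, 6 rose, 2 fell and 15 did not pass among 23 (adjusted over the list alone, 6 and 2). SELE, VCAM1, ICAM1, CD47 (1.27), JAM2 (1.0) and CD44 (0.72) rose, and CD34 (-0.87) and ICAM2 (-0.69) fell. The adhesion median was 0.05 (batch term 0.05, high -0.05, low 0.09). For adhesion genes camera gave adjusted p = 0.00370, lost with an estimated correlation, adjusted p = 0.193. Of the Toll-like receptor genes, 7 rose, 0 fell and 23 did not pass among 30 (adjusted over the list alone, 8 and 3), with MAP3K8 (2.56), TLR2 (2.54) and IRAK2 (1.70) the most changed. The Toll-like receptor median was 0.08 (batch term 0.08, high 0.10, low 0.07). For Toll-like receptor genes camera gave adjusted p = 5.28e-04, or 0.00434 with an estimated correlation. Of the immediate early genes, 6 rose, 2 fell and 16 did not pass among 24 (adjusted over the list alone, 7 and 4): SOCS1 (1.57) and JUNB (1.35) rose and SOCS2 (-1.28) and DUSP4 (-0.69) fell, 1 of 2 other SOCS1 probe sets having the same sign. The immediate early median was 0.21 (batch term 0.21, high 0.21, low 0.21). For immediate early genes camera gave adjusted p = 0.00970, or 0.0221 with an estimated correlation. Of the oxidative stress genes, 6 rose, 1 fell and 22 did not pass among 29 (adjusted over the list alone, 7 and 2), the cystine transporter SLC7A11 (1.39) and heme oxygenase HMOX1 (1.03) having risen with SOD2 and the oxidase NOX4 (-0.42) having fallen. The oxidative stress median was 0.12 (batch term 0.12, high 0.11, low 0.22). For oxidative stress genes camera gave adjusted p = 0.0163, lost with an estimated correlation, adjusted p = 0.328.

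The other lists did not pass camera's test at 8 h. Of the coagulation genes 5 of 20 rose and 2 fell (adjusted over the list alone 5 and 3, camera adjusted p = 0.804): F3, SERPINE2 (0.96), PLAT (0.73), PLAUR (0.66) and TFPI2 (0.46) were higher and THBD and PROCR (-0.5) lower. Among the junction proteins 2 of 21 rose and 4 fell (adjusted over the list alone 2 and 6, camera adjusted p = 0.340), with CLDN1 (2.04) and AFDN (0.39) higher and GJA4 (-1.88), ESAM (-1.11), OCLN (-0.68) and PKP4 (-0.66) lower. Of the barrier regulators 6 of 36 rose and 5 fell (adjusted over the list alone 7 and 5, camera adjusted p = 0.101), with PTGS2 (1.92) and VEGFC (1.64) higher and NOS3, APLN (-0.97), NRP1 (-0.67), CALCRL (-0.64) and ROBO4 (-0.33) lower. Among the apoptosis regulators 6 of 31 rose and 1 fell (adjusted over the list alone 8 and 6, camera adjusted p = 0.326), with RIPK2 (1.88) and CASP1 (0.95) higher and the death receptor FAS (-0.49) lower. Of the unfolded protein genes 1 of 26 rose and 1 fell (adjusted over the list alone 0 and 0, camera adjusted p = 0.379), these being CEBPB (0.69) and SESN2 (-0.39). Of the cholesterol genes 0 of 21 rose and 1 fell (adjusted over the list alone 0 and 0, camera adjusted p = 0.357), the latter being TM7SF2 (-0.67). Of the matrix genes 5 of 36 rose and 1 fell (adjusted over the list alone 5 and 1, camera adjusted p = 0.103), with the proteases MMP10 (4.31), MMP1 (2.18) and ADAMTS9 (1.21) higher and LAMA4 (-0.38) lower.

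Of the markers of other cell types at 8 h, among leukocyte markers 0 of 8 rose and 0 fell (adjusted over the list alone 0 and 0, 1 and 1 at unadjusted p under 0.05, camera adjusted p = 0.763) and among fibroblast markers 1 of 11 rose and 1 fell (adjusted over the list alone 1 and 2, camera adjusted p = 0.921). The collagen COL3A1 (0.76) rose and POSTN (-0.70) fell, but the other COL3A1 probe set moved the opposite way, and without probe sets ending in _x_at the COL3A1 value was -0.27. Of the smooth muscle markers 0 of 9 rose and 0 fell (adjusted over the list alone 0 and 0, 0 and 0 at unadjusted p under 0.05, camera adjusted p = 0.818) and of the epithelial markers 0 of 6 rose and 0 fell (adjusted over the list alone 0 and 0, 0 and 0 at unadjusted p under 0.05, camera adjusted p = 0.902). The median, mean and test differed in sign for the coagulation, apoptosis, matrix and fibroblast lists.

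At 8 h 1546 of 14404 genes were called, 664 higher and 882 lower, and 312 of them changed at least 2-fold, 197 higher and 115 lower. The LPS and control arrays did not overlap for 1317 of the called genes and for 13.2% of the genes tested, against 2.86% by chance. With the batch term 1679 genes were called, 1534 of the 1546 among them, and the high arrays alone (3 against 3) gave 794 and the low arrays alone (1 against 1) 103. A fit on the 8 arrays of the comparison alone gave 775 calls. With each array shifted to the same median 790 were higher and 654 lower. Of the 90 called genes named for 8 h, 89 were still called with the batch term, and the call was lost for COLEC12 (adjusted p = 0.0512). Leaving out 1 array ended this call and those of AFDN, CALCRL, CD34, CEBPB, COL3A1, DLL4, DUSP4, FAS, LAMA4, NOX4, NRP1, OCLN, ROBO4, SESN2 and TM7SF2 in 1 to 7 of the 8 fits each (adjusted p up to 0.2). Averaging all probe sets of a gene ended those of CD44, COL3A1, FAS, NRP1 and OCLN, and the fit on the 8 arrays alone also those of ICAM2, OAS1, PKP4, PLAT, POSTN, PROCR and TFPI2. High or low arrays differed from all arrays by over 1.5 times for FAS (-0.58, -0.22), ICAM2 (-0.85, -0.22) and NOS3 (-1.81, -0.92). Others were PKP4 (-0.80, -0.25), PLAT (0.90, 0.25), ROBO4 (-0.41, -0.09), SERPINE2 (1.11, 0.51), SOD2 (2.10, 0.15) and TFPI2 (0.52, 0.31).

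**Figure D3:**
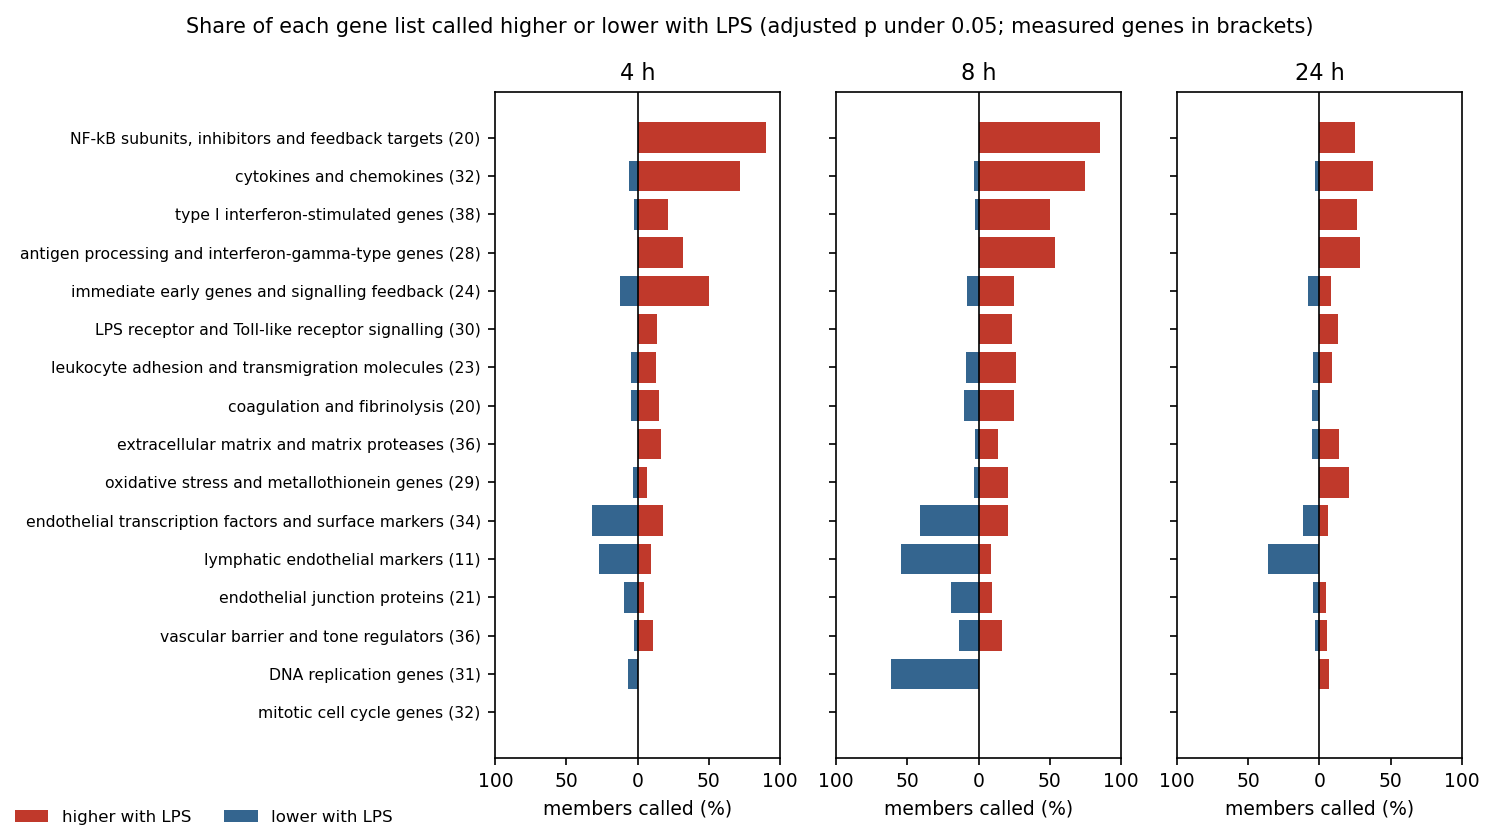
Share of the measured members of 16 gene lists (percent) called higher (red, to the right) or lower (blue, to the left) with LPS at 4, 8 and 24 h, with the number measured in brackets. Of the 31 replication genes 19 were lower at 8 h and 2 at 4 h, and of the 20 NF-kB genes 18, 17 and 5 were higher at 4, 8 and 24 h.

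After 24 h of LPS SELE, 4 chemokines and the protease MMP10 had the highest changes, and B3GALT2 and elastin the lowest. SELE rose from 10.7 ± 6.90 to 886 ± 737, by 4.83 ± 0.34 (adjusted p = 5.47e-09). The chemokines CXCL6, CXCL2, CXCL1 and CXCL5 rose by 4.52 ± 0.23, 4.31 ± 0.23, 3.27 ± 0.26 and 3.25 ± 0.27, and the matrix protease MMP10 by 2.97 ± 0.23. The other CXCL2 probe sets gave 0.06 and 0.83, and those of CXCL5, also read from an _x_at probe set, 0.5 and 2.69. A group mean lay under the filter value of 16.006 for SELE, ELN, ADAMTS1, B3GALT2, IFIT1, MAP3K8, SOCS1, TLR2, TLR3 and TNIP3, so that their values depend on the pseudocount: with 1 and 64 in place of 16 SELE was 6.13 and 3.42 and ELN was -4.68 and -1.69. VCAM1 (0.07 ± 0.31) and F3 (-0.03 ± 0.19) did not pass at 24 h. ELN, the elastic fibre protein, fell by 2.99 ± 0.47 from 183 ± 123 to 5.55 ± 3.77 (adjusted p = 4.24e-04), and B3GALT2, a galactosyltransferase, fell by 3.21 ± 0.40 (adjusted p = 1.86e-05). The next lowest were the scavenger receptor COLEC12 (-2.02), GJA4 (-1.98), DCLK1 (-1.88) and the cell cycle inhibitor CDKN1C (-1.86).

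In the panel CXCL8 rose by 2.92 ± 0.30, SOD2 by 2.73 ± 0.38, ICAM1 by 1.80 ± 0.16, IL6 by 1.5 ± 0.21, CCL2 by 1.03 ± 0.19 and NFKBIA by 0.72 ± 0.15. CDH5 (0.03 ± 0.12), NOS3 (-0.19 ± 0.23), THBD (0.10 ± 0.10) and TLR4 (-0.63 ± 0.20) did not pass. Under other settings CDH5, NOS3, THBD and VCAM1 changed sign. TLR4 passed as lower with all probe sets averaged (adjusted p = 0.0280), without control 24 h replicate 3 (0.0319) and in 4 other settings (0.0219 to 0.0417), and not with the batch term (0.182).

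Of the cytokines and chemokines, 12 rose, 1 fell and 19 did not pass among 32 (adjusted over the list alone, 18 and 2), TNFSF18 (-1.24) having fallen. The cytokine median was 0.57 (batch term 0.48, high 0.53, low 0.48). For cytokine genes camera gave adjusted p = 1.08e-17, or 0.00199 with an estimated correlation. Antigen processing genes included the immunoproteasome subunits PSMB9 (1.03) and PSMB10 (1.0) and the peptide loading factor TAPBP (0.90): 8 rose, 0 fell and 20 did not pass among 28 (adjusted over the list alone, 16 and 0). The antigen processing median was 0.43 (batch term 0.39, high 0.42, low 0.42). For antigen processing genes camera gave adjusted p = 1.06e-14, or 0.00365 with an estimated correlation. Of the type I interferon-stimulated genes, 10 rose, 0 fell and 28 did not pass among 38 (adjusted over the list alone, 18 and 0), among them IFI35 (0.97), IFIT1 (0.92) and SP110 (0.72). The interferon median was 0.36 (batch term 0.31, high 0.32, low 0.33). For interferon genes camera gave adjusted p = 2.17e-13, or 1.72e-05 with an estimated correlation. Among the NF-kB genes, 5 rose, 0 fell and 15 did not pass among 20 (adjusted over the list alone, 8 and 0): NFKBIZ (1.48), TNIP3 (1.07), NFKBIA (0.72), TNFAIP3 (0.64) and TNIP1 (0.46) rose. The NF-kB median was 0.33 (batch term 0.22, high 0.34, low 0.36). For NF-kB genes camera gave adjusted p = 2.96e-06, lost with an estimated correlation, adjusted p = 0.0709. Of the Toll-like receptor genes, 4 rose, 0 fell and 26 did not pass among 30 (adjusted over the list alone, 5 and 1), namely MAP3K8 (1.49), TLR2 (0.95), TLR3 (0.87) and IRAK3 (0.60), 1 of 2 other IRAK3 probe sets having the same sign. The Toll-like receptor median was 0.07 (batch term 0.07, high 0.17, low 0.07). For Toll-like receptor genes camera gave adjusted p = 0.0387, lost with an estimated correlation, adjusted p = 0.0715, passing with the batch term as well, adjusted p = 0.0344. That call was also lost with a pseudocount of 64 (adjusted p = 0.0557).

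Of the leukocyte adhesion molecules, 2 rose, 1 fell and 20 did not pass among 23 (adjusted over the list alone, 6 and 1). SELE and ICAM1 rose and the sialomucin PODXL (-0.55) fell. The adhesion median was 0.16 (batch term -0.02, high 0.02, low 0.20). For adhesion genes camera gave adjusted p = 0.0301, lost with an estimated correlation, adjusted p = 0.336. The adhesion call was also lost with the batch term (adjusted p = 0.336) and after quantile normalization (adjusted p = 0.171). Of the lymphatic markers, 0 rose, 4 fell and 7 did not pass among 11 (adjusted over the list alone, 0 and 6), namely COLEC12 (-2.02), MAF (-1.23), PROX1 (-0.86) and TFF3 (-0.70), 2 of 3 other PROX1 probe sets having the same sign. The lymphatic median was -0.55 (batch term -0.42, high -0.18, low -0.49). For lymphatic genes camera gave adjusted p = 7.66e-05, lost with an estimated correlation, adjusted p = 0.0628. Of the oxidative stress genes, 6 rose, 0 fell and 23 did not pass among 29 (adjusted over the list alone, 7 and 0): SOD2, CYBA (0.47) and the metallothioneins MT1G (1.13), MT1H (0.92), MT1M (0.92) and MT1F (0.82) rose, the other CYBA probe set giving -0.19 and the metallothioneins being close paralogs. The oxidative stress median was 0.17 (batch term 0.12, high 0.06, low 0.27). For oxidative stress genes camera gave adjusted p = 7.66e-05, lost with an estimated correlation, adjusted p = 0.0989.

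Of the matrix genes and proteases, 5 rose, 2 fell and 29 did not pass among 36 (adjusted over the list alone, 13 and 2), with MMP10 (2.97), ADAMTS1 (1.82) and MMP1 (1.07) the most changed and NID1 (-0.78) and INHBA (-0.70) lower. The matrix median was 0.20 (batch term -0.05, high 0.01, low 0.04). For matrix genes camera gave adjusted p = 0.00138, lost with an estimated correlation, adjusted p = 0.180. With the batch term the matrix call was lost (adjusted p = 0.0864). Of the DNA replication genes, 2 rose, 0 fell and 29 did not pass among 31 (adjusted over the list alone, 2 and 0). They were CCNE1 (0.69) and CDC45 (0.60). The replication median was 0.21 (batch term 0.23, high 0.00, low 0.26). For replication genes camera gave adjusted p = 9.86e-05, lost with an estimated correlation, adjusted p = 0.328. Of the apoptosis regulators, 3 rose, 2 fell and 26 did not pass among 31 (adjusted over the list alone, 3 and 2), with the inflammatory caspase CASP1 (1.41), TNFRSF1A (0.76) and TNFRSF1B (0.5) higher and BCL2L11 (-1.0) and GADD45B (-0.65) lower. The apoptosis median was 0.14 (batch term 0.11, high -0.01, low 0.20). For apoptosis genes camera gave adjusted p = 0.0157, lost with an estimated correlation, adjusted p = 0.188. Of the unfolded protein and amino acid stress genes, 1 rose, 0 fell and 25 did not pass among 26 (adjusted over the list alone, 3 and 0), the riser being the asparagine synthetase ASNS (0.70). The unfolded protein median was 0.13 (batch term 0.03, high 0.14, low 0.05). For unfolded protein genes camera gave adjusted p = 0.0434, lost with an estimated correlation, adjusted p = 0.309. This call was also lost with the batch term (adjusted p = 0.246) and after quantile normalization (adjusted p = 0.149). Of the cholesterol genes, 0 rose, 0 fell and 21 did not pass among 21 (adjusted over the list alone, 0 and 0; at unadjusted p under 0.05, 9 and 1). The cholesterol median was 0.26 (batch term 0.25, high 0.08, low 0.39). For cholesterol genes camera gave adjusted p = 6.35e-04, lost with an estimated correlation, adjusted p = 0.188.

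The remaining lists did not pass camera's test at 24 h. Of the immediate early genes 2 of 24 rose and 2 fell (adjusted over the list alone 2 and 5, camera adjusted p = 0.326): SOCS3 (1.96) and SOCS1 (1.25) were higher and SOCS2 (-0.87) and SPRY2 (-0.52) lower. Of the coagulation genes 0 of 20 rose and 1 fell (adjusted over the list alone 1 and 1, camera adjusted p = 0.804), the latter being GAS6 (-0.68). Of the junction proteins 1 of 21 rose and 1 fell (adjusted over the list alone 2 and 3, camera adjusted p = 0.611), these being CLDN1 (0.89) and GJA4 (-1.98). Of the barrier regulators 2 of 36 rose and 1 fell (adjusted over the list alone 6 and 5, camera adjusted p = 0.921): PTGS2 (1.07) and VEGFC (0.79) were higher and SPHK1 (-0.57) lower. Of the endothelial factors and markers 2 of 34 rose and 4 fell (adjusted over the list alone 5 and 8, camera adjusted p = 0.216): GATA2 (0.69) and CD93 (0.64) were higher and HEY1 (-0.76), HES1 (-0.56), MEF2C (-0.53) and FOXC2 (-0.41) lower, 1 of 2 other GATA2 probe sets having the same sign. Of the mitotic genes 0 of 32 rose and 0 fell (adjusted over the list alone 0 and 0, 1 and 0 at unadjusted p under 0.05, camera adjusted p = 0.804). Among the markers of other cell types, for leukocytes 0 of 8 rose and 0 fell (adjusted over the list alone 0 and 0, 0 and 1 at unadjusted p under 0.05, camera adjusted p = 0.611), for fibroblasts 0 of 11 rose and 1 fell (adjusted over the list alone 0 and 1, camera adjusted p = 0.0903), for smooth muscle 0 of 9 rose and 0 fell (adjusted over the list alone 0 and 1, 0 and 1 at unadjusted p under 0.05, camera adjusted p = 0.263) and for epithelium 0 of 6 rose and 0 fell (adjusted over the list alone 0 and 0, 1 and 0 at unadjusted p under 0.05, camera adjusted p = 0.890). The fibroblast gene that fell was COL1A2 (-0.76), 1 of 2 other COL1A2 probe sets having the same sign, and with the batch term the fibroblast list passed as lower (adjusted p = 0.0272), a call lost with an estimated correlation (adjusted p = 0.0734).

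At 24 h 482 of 14404 genes were called, 237 higher and 245 lower, and 113 of them changed at least 2-fold, 67 higher and 46 lower. The arrays did not overlap for 433 of the called genes and for 9.34% of the genes tested, against 2.86% by chance. With the batch term 378 genes were called, 341 of the 482 among them, and the high arrays alone (3 against 1) gave 24 and the low arrays alone (1 against 3) 12. Single arrays moved this count by over 1.5 times: it was 272 without LPS 24 h replicate 1, 314 without LPS 24 h replicate 4, 245 without control 24 h replicate 1 and 241 without control 24 h replicate 2. A fit on the 8 arrays compared alone gave 196, and CXCL2 was at 0.83 and not called without probe sets ending in _x_at. Of the 76 called genes named for 24 h, 66 were still called with the batch term, and the call was lost for BCL2L11, CDC45, GATA2, HEY1, IFIT1, MT1F, MT1M, SPHK1, TNFAIP3 and TNIP1 (adjusted p = 0.0518 to 0.121). Leaving out 1 array ended these calls and those of CCNE1, CLDN1, CYBA, FOXC2, GAS6, HES1, INHBA, IRAK3, MEF2C, MT1H, PODXL, PROX1, TFF3 and TNFRSF1B in 1 to 8 of the 8 fits each (adjusted p up to 0.206). Averaging all probe sets of a gene ended those of ASNS, BCL2L11, CCNE1, COL1A2, CYBA, GATA2, HES1, HEY1, IRAK3, MT1G, SOCS1 and TNIP1, and the fit on the 8 arrays alone also those of CD93, NFKBIA, PTGS2 and TLR2. High or low arrays differed from all arrays by over 1.5 times for ASNS (0.39, 0.89), CD93 (0.32, 0.64) and CDKN1C (-1.16, -2.12). Others were CLDN1 (0.55, 1.09), HEY1 (-0.44, -0.87), IRAK3 (1.11, 0.28), MAF (-0.68, -1.37), MT1F (0.32, 0.87) and MT1H (0.44, 0.70). So were MT1M (0.31, 1.30), NFKBIA (0.45, 0.74), PODXL (-0.43, -0.93), SOD2 (3.34, 1.67), TLR2 (0.64, 1.53) and TNFAIP3 (0.33, 0.62). For COLEC12 high and low arrays gave -1.35 and -2.48.

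Whether the LPS change itself differed between times was tested as an interaction. From 4 to 8 h it fell for IL6, with a difference of -3.92 ± 0.30 (adjusted p = 3.01e-08). It also fell for C11orf96 (-3.79 ± 0.29), the cytokine LIF (-3.0 ± 0.22) and F3 (-2.87 ± 0.27). It rose by 2.01 ± 0.28 for the hyaluronan-binding protein CEMIP (adjusted p = 2.05e-04), by 1.84 ± 0.21 for the amino acid transporter SLC7A2 and by 1.66 ± 0.39 for the chemokine CXCL5, 0.99 on the low arrays, a call that ended with a pseudocount of 1 and in 7 of the fits without 1 array (adjusted p up to 0.0697). The monooxygenase CYP1A1, whose LPS change was -1.17 at 4 h and 0.46 at 8 h (0.75 and called without control 8 h replicate 3), rose by 1.63 ± 0.32. In all 210 genes differed, 85 upward and 125 downward (195 with the batch term, 9 on the high and 2 on the low arrays).

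Among the lists, from 4 to 8 h the interferon list moved up (median 0.26, batch term 0.30, high 0.37, low 0.25, camera adjusted p = 1.13e-06, or 0.00149 with an estimated correlation), and the immediate early list (median -0.49, batch term -0.48, high -0.47, low -0.5, camera adjusted p = 1.13e-10, or 1.97e-05 with an estimated correlation) and the coagulation list (median -0.25, batch term -0.17, high -0.07, low -0.17, camera adjusted p = 8.06e-04, or 0.0238 with an estimated correlation) moved down, which held with the batch term. With an estimated correlation the NF-kB (adjusted p = 0.147), cytokine (0.409), antigen processing (0.360) and replication lists (0.271) lost the call that the preset correlation gave. Median, mean and test differed in sign for the adhesion, Toll-like receptor, mitotic, apoptosis, leukocyte and smooth muscle lists.

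From 8 to 24 h the LPS change fell for VCAM1, with a difference of -5.34 ± 0.43 (adjusted p = 7.22e-08). It fell as well for CCL20 (-4.65 ± 0.36), the hyaluronan-modifying TNFAIP6 (-3.74 ± 0.38) and lymphotoxin beta, LTB (-3.66 ± 0.32). It rose by 1.97 ± 0.33 for the complement protease C1S (adjusted p = 9.07e-04), by 1.83 ± 0.29 for the phosphatase DUSP23 and by 1.79 ± 0.42 for the matrix protease ADAMTS1. For LIMCH1 it rose by 1.68 ± 0.18, 2 of 3 other LIMCH1 probe sets having the same sign. In all 418 genes differed, 206 upward and 212 downward (447 with the batch term, 31 on the high and 2 on the low arrays). With each array shifted to the same median 139 were upward and 254 downward, and a fit on the 16 arrays compared alone gave 226, ADAMTS1 not among them. C1S was not called with a pseudocount of 1.

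The NF-kB list (median -0.98, batch term -1.0, high -1.03, low -0.96, camera adjusted p = 6.60e-31, or 2.05e-04 with an estimated correlation), the cytokine list (median -0.82, batch term -0.98, high -1.18, low -0.97, camera adjusted p = 1.24e-18, or 0.00191 with an estimated correlation) and the immediate early list (median -0.27, batch term -0.28, high -0.22, low -0.34, camera adjusted p = 0.00403, or 0.0151 with an estimated correlation) moved down from 8 to 24 h, and the replication list moved up (median 0.83, batch term 0.88, high 0.66, low 0.91, camera adjusted p = 2.26e-21, or 0.0274 with an estimated correlation), which held with the batch term. Of the replication genes 15 of 31 differed upward (25 adjusted over the list alone). With an estimated correlation the adhesion (adjusted p = 0.439), interferon (0.103), antigen processing (0.263), Toll-like receptor (0.0958) and cholesterol lists (0.269) lost the call that the preset correlation gave. The barrier list passed with the batch term (adjusted p = 0.0337), lost with an estimated correlation (adjusted p = 0.140). Median, mean and test differed in sign for the adhesion, junction, matrix, leukocyte and epithelial lists.

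From 4 to 24 h the LPS change fell for VCAM1, with a difference of -5.26 ± 0.43 (adjusted p = 2.73e-08), for CXCL3 (-4.97 ± 0.25), F3 (-4.96 ± 0.27) and IL6 (-4.92 ± 0.30). It rose by 2.79 ± 0.33 for C1S (adjusted p = 7.13e-06), by 2.52 ± 0.33 for the central complement protein C3 (3.17 on the high and 1.69 on the low arrays), by 1.98 ± 0.40 for the phospholipase PLA1A and by 1.82 ± 0.29 for DUSP23. In all 650 genes differed, 306 upward and 344 downward (704 with the batch term, 38 on the high and 67 on the low arrays). Scaling mattered here, since shifting each array to the same median moved the median of all genes from 0.08 to -0.03 and the counts to 157 upward and 439 downward, and quantile normalization gave 208 and 381.

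The NF-kB (median -1.35, batch term -1.35, high -1.27, low -1.56, camera adjusted p = 5.42e-38, or 6.95e-05 with an estimated correlation), cytokine (median -1.08, batch term -1.08, high -1.19, low -0.93, camera adjusted p = 5.68e-19, or 0.00191 with an estimated correlation), immediate early (median -0.54, batch term -0.54, high -0.55, low -0.67, camera adjusted p = 6.43e-15, or 3.09e-06 with an estimated correlation) and coagulation lists (median -0.19, batch term -0.19, high -0.28, low -0.32, camera adjusted p = 0.00204, or 0.0349 with an estimated correlation) moved down from 4 to 24 h, which held with the batch term. With an estimated correlation the adhesion (adjusted p = 0.360), barrier (0.104), replication (0.307) and fibroblast lists (0.191) lost the call that the preset correlation gave. Median, mean and test differed in sign for the antigen processing, junction, unfolded protein and leukocyte lists.

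More calls were shared between times than if independent. Of the genes higher at 4 h (524) and at 8 h (664), 310 were shared against 24.2 for independent calls, and of those lower (660 and 882) 257 against 40.4. Between 8 and 24 h 129 higher genes were shared against 10.9 and 125 lower against 15, and between 4 and 24 h 73 against 8.62 and 68 against 11.2. These comparisons share no arrays. In all 2348 genes were called at some time and 130 at all 3 times, 67 of them higher and 57 lower at each.

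The controls without LPS gave the background of time in culture. From 4 to 24 h FLT1, a receptor for vascular endothelial growth factor, fell by 3.38 ± 0.20 from 635 ± 76.3 to 46.2 ± 4.82 (adjusted p = 7.64e-11), as did the histone deacetylase HDAC9 (-2.72 ± 0.16), the neuron navigator NAV3 (-2.60 ± 0.28) and the ubiquitin ligase HECW2 (-2.31 ± 0.12). B3GALT2 rose by 2.35 ± 0.40, LOC441179 by 1.90 ± 0.34, GJA4 by 1.80 ± 0.32 and the cholesterol hydroxylase CH25H by 1.77 ± 0.23, 1 of 2 other HDAC9 probe sets having the same sign. At 8 h against 4 h the changes were FLT1 (-2.59), HDAC9 (-2.24), NAV3 (-2.25) and HECW2 (-1.53), all of which passed, HDAC9 not with all probe sets averaged. Those of the 4 genes that rose did not pass, though 3 of them did under other settings.

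Between control 4 h and 24 h 1243 genes differed, 630 higher and 613 lower at 24 h, with 1341 under the batch term, 692 on the low arrays (3 against 3) and 7 on the high arrays, where 1 array stood against 1. The count was 814 without control 4 h replicate 4, 798 without control 24 h replicate 1 and 769 without control 24 h replicate 2. Between control 4 h and 8 h 640 genes differed, 296 higher and 344 lower at 8 h, with 566 under the batch term, 26 on the high (3 against 1) and 4 on the low arrays (1 against 3). It was 390 without control 4 h replicate 4, and with each array shifted to the same median 223 were higher and 408 lower.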

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

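The tests of the low spike-in arrays, the permutations with LPS and time effects removed and the second draw of relabellings were chosen only after the results were seen. A single array stood apart from the other 3 of its group for 41 of 601 combinations of a named gene and a group (6.82%), by the gap to its nearest neighbour over the range of the group, given in brackets below, above Dixon's critical value for 4 samples. Chance gives about 1 in 20 such groups. LPS 24 h replicate 3 was highest for CASP1 (0.941), CEBPD (0.962), ELN (0.940), MMP1 (0.905), MMP10 (0.840), SELE (0.924) and SOCS1 (0.843) and lowest for ADAMTS1 (0.902) and ASNS (0.877). control 4 h replicate 1 was highest for C3 (0.842) and ROCK2 (0.905) and lowest for SOCS2 (0.835) and C11orf96 (0.937). control 8 h replicate 3 was highest for COL3A1 (0.835), CYP1A1 (0.899) and SLC2A12 (0.889) and lowest for CXCL8 (0.907), LPS 4 h replicate 4 was highest for C1S (0.908), MCL1 (0.979) and ROCK2 (0.911) and control 4 h replicate 4 was highest for VEGFC (0.871) and lowest for SAMD9L (0.886) and TGFB2 (0.939). control 8 h replicate 1 was highest for F3 (0.891) and MCM10 (0.918) and lowest for CXCL3 (0.863), LPS 24 h replicate 2 was lowest for GAS6 (0.987), IFI35 (0.900) and MAF (0.901) and control 24 h replicate 3 was highest for NOS3 (0.904) and TNIP3 (0.941) and lowest for GATA2 (0.914). LPS 8 h replicate 2 was highest for PROX1 (0.956) and lowest for HMOX1 (0.949), LPS 4 h replicate 2 was highest for CSF3 (0.871) and control 4 h replicate 3 was highest for CXCL2 (0.864). LPS 4 h replicate 1 was highest for IFIH1 (0.860), control 8 h replicate 2 was lowest for MAP3K8 (0.832) and control 24 h replicate 2 was highest for CFB (0.854). LPS 24 h replicate 1 was lowest for CXCL3 (0.897) and control 24 h replicate 1 was lowest for HECW2 (0.872).

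The LPS change differed between times by limma's test for 210 genes between 4 and 8 h, 418 between 8 and 24 h and 650 between 4 and 24 h, and 118 of the 186 named genes had such a difference. From 4 to 8 h the differences were 2.01 for CEMIP, 1.84 for SLC7A2, 1.66 for CXCL5, 1.63 for CYP1A1, -3.92 for IL6, -3.79 for C11orf96, -3.0 for LIF and -2.87 for F3. Between 8 and 24 h they were 1.97 for C1S, 1.83 for DUSP23, 1.79 for ADAMTS1, 1.68 for LIMCH1, -5.34 for VCAM1, -4.65 for CCL20, -3.74 for TNFAIP6 and -3.66 for LTB. Those between 4 and 24 h were 2.79 for C1S, 2.52 for C3, 1.47 for C1R, 1.98 for PLA1A, 1.82 for DUSP23, -5.26 for VCAM1, -4.97 for CXCL3, -4.96 for F3 and -4.92 for IL6. Lists differed between 4 and 8 h for interferon (camera adjusted p = 1.13e-06), immediate early (1.13e-10) and coagulation genes (8.06e-04). Between 8 and 24 h they did for NF-kB (6.60e-31), cytokine (1.24e-18), immediate early (0.00403) and replication genes (2.26e-21), and between 4 and 24 h for NF-kB (5.42e-38), cytokine (5.68e-19), immediate early (6.43e-15) and coagulation genes (0.00204).

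Chance as the source of these counts of differences was tested by relabelling time within LPS and within control arrays, the real labelling being 1 of 100 drawn. As many genes were called in 6 of 100 between 4 and 8 h (210 genes, highest other 385), 4 of 100 between 8 and 24 h (418, highest other 623) and 6 of 100 between 4 and 24 h (650, highest other 2229). The shares lie around 5% and change with the draw, a second giving 3, 4 and 8 of 100 (highest others 288, 1132 and 1802). The highest other count between 4 and 24 h was several times the real count. Relabellings that gave as many genes moved at least 2 more arrays across times in 1 treatment than in the other. They thus carry the difference between times itself, so this test cannot exclude chance for any pair. With LPS and time effects removed first, 1 of 100 permutations, the real one, gave as many genes in each comparison (highest others 81, 3 and 385). That is the smallest share 100 permutations can give, and it argues against chance there without excluding it.

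For the comparisons between 2 groups, 1 of the 35 splits of the 8 arrays, the real one, gave as many called genes in each, which excludes chance as the source of those counts. The real counts and the highest of the other splits were 1184 and 0 for LPS at 4 h, 1546 and 3 at 8 h, 482 and 12 at 24 h, 640 and 145 for control 8 h against 4 h, and 1243 and 1 for control 24 h against 4 h. The split with 145 genes was the one that set low against high spike-in arrays, and with the batch as a covariate control 8 h against 4 h gave 566 genes. The 26 genes on the high arrays and 4 on the low arrays come from 3 arrays against 1 and decide nothing.

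Low spike-in arrays went partly with the control groups at 4 and 24 h. The array batch as the whole source of the LPS calls is argued against, since 81.9% of the genes called at 4 h and 70.7% of those called at 24 h were still called in the same direction with the batch as a covariate. RNA degradation on the low arrays is argued against as well, since the log2 ratio of 3' to 5' signal of GAPDH and ACTB was not higher there (-0.00 ± 0.05, n = 10, against 0.08 ± 0.06, n = 14, mean ± SD, a difference of -0.080). Compression of the brightest signals on the low arrays cannot be told apart from the division itself, which was chosen knowing that the highest signals divided the arrays in the same way: the brightest 1% of genes had a median batch difference of -0.59 and genes of middling signal 0.02, a difference of -0.62. A difference between cultures was not tested.

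Probe sets without a single gene symbol were left out of the comparisons. Tested on their own, 139 of 6175 differed with LPS at 4 h (92 higher and 47 lower), 127 at 8 h (63 and 64) and 43 at 24 h (22 and 21).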

How the results depend on the processing

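The tests with the array batch were chosen only after the results were seen. Over the settings run for 310 results of named genes, 7050 values kept direction and side of the threshold, 837 kept direction but no longer passed, 25 passed newly, of TLR4, GJA4, CH25H, B3GALT2, CYP1A1 and C3, and 19 changed sign. Of the 288 called results 230 kept their call in every fit that left out 1 array and 90 in every setting run. Of the list tests 376 kept direction and side, 31 were lost and 7 gained, 0 reversing. Leaving out 1 array gave 935 to 1068 genes changed by LPS at 4 h, 1193 to 1460 at 8 h and 241 to 566 at 24 h, 143 to 226, 284 to 471 and 485 to 672 for the differences 4 to 8, 8 to 24 and 4 to 24 h, 390 to 690 for control 8 h against 4 h and 769 to 1209 for control 24 h against 4 h. With every probe set tested, which tests more features, counts were 1824 at 4 h, 2327 at 8 h, 1186 for control 8 h and 2391 for control 24 h against 4 h, and at least 2-fold 484, 551 and 194 at 4, 8 and 24 h. The arrays compared alone, fewer samples, gave 775 at 8 h, 196 at 24 h, 226 between 8 and 24 h and 339 for control 8 h against 4 h. Array quality weights gave 1854 at 4 h, 886 at 24 h, 1170 between 4 and 24 h, 1013 for control 8 h and 2064 for control 24 h, and the cause was not tested. The high arrays alone, fewer samples, gave 203, 794 and 24 genes at 4, 8 and 24 h (24 at least 2-fold at 24 h), 9, 31 and 38 for the differences 4 to 8, 8 to 24 and 4 to 24 h, and 26 and 7 for the controls. The low arrays alone gave 303, 103 and 12 (103 and 12 at least 2-fold at 8 and 24 h), 2, 2 and 67, and 4 and 692. Apart from 794 and 692, these fits have a group of 1 array, assumed to vary like the other groups. A pseudocount of 1 gave 381 genes at least 2-fold at 4 h, and 64 gave 151, 169 and 55 at 4, 8 and 24 h, as signal over background limits the folds of weak genes. Some small values that did not pass changed sign, as did COL3A1, and the cause was not tested unless the setting holds fewer samples. At 4 h C3 was -0.61, C1S -0.14 and NFKBIB -0.069 on the high arrays, C3 was -0.078 without LPS 4 h replicate 4 (range -0.078 to 0.28 leaving out 1 array), and NOS3 was 0.012 with all probe sets averaged, while COL3A1 at 8 h was -0.27 without probe sets ending in _x_at. CDH5 at 8 h was 0.067 on the low arrays and 0.027 without control 8 h replicate 3 (range -0.17 to 0.027 leaving out 1 array). CDH5 at 24 h was -0.070 after quantile normalization, -0.069 with the batch as a covariate, -0.11 on the high arrays, -0.015 without LPS 24 h replicate 1 and -0.0050 without control 24 h replicate 1 (range -0.015 to 0.075). NOS3 at 24 h was 0.48 on the low arrays and THBD -0.14 on the high arrays. VCAM1 at 24 h was -0.090 with array quality weights, -0.021 with the batch as a covariate, -0.21 on the low arrays and -0.38 without LPS 24 h replicate 3 (range -0.38 to 0.29). Replicate numbers did not pair the samples, since pairs with the same number correlated at r of -0.15 to 0.20, over 0.1 in 3 of 12 pairs, and 3 of 24 arrays correlated best with their own number. With a replicate block counts were 1129, 1437 and 400 at 4, 8 and 24 h, 194, 339 and 563 for the differences 4 to 8, 8 to 24 and 4 to 24 h, and 566 and 1123 for the controls, and the correlation as a random effect was -0.03. Camera with the block lost the unfolded protein list at 24 h (adjusted p = 0.0539). By fry, whose test does not compare a list with other genes, the endothelial list at 4 h (adjusted p = 0.00378), the junction (0.0172), barrier (0.00285) and matrix (0.0108) lists at 8 h and the fibroblast list at 24 h (0.0249) passed, and the replication list at 4 h (0.0571) and 24 h (0.0802) and the oxidative stress list at 8 h (0.0511) did not. Other list values that changed stand beside their lists.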

Other observations

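The complement genes were chosen only after their values were seen, and the culture time and SPIDR patterns were noticed in the data before their tests were set. Complement, the plasma cascade that opsonises microbes, was not among the fixed lists, and 13 of its genes were measured. Those called were 2 at 4 h, 4 at 8 h and 4 at 24 h, the 4 at 24 h higher with LPS. C3, the cascade's central component, changed by 0.10 ± 0.24, 1.54 ± 0.24 and 2.62 ± 0.24 at 4, 8 and 24 h (adjusted p = 1.83e-07 at 24 h, n = 4 arrays per group, limma). The proteases of the classical pathway C1S and C1R changed by 0.08 ± 0.23, 0.90 ± 0.23 and 2.87 ± 0.23, and by 0.96 ± 0.25, 1.96 ± 0.25 and 2.43 ± 0.25. CFB, the protease of the alternative pathway, changed by 1.95 ± 0.35, 2.58 ± 0.35 and 2.73 ± 0.35. The change differed between 4 and 24 h for C3 (adjusted p = 3.20e-05), C1S (adjusted p = 7.13e-06) and C1R (adjusted p = 0.0169), and not for CFB (a difference of 0.79, adjusted p = 0.460). C3 and C1S at 4 h did not pass, C3 being -0.61 on the high and 0.82 on the low arrays. C1R at 4 h was 0.27 and 1.43 there, and its call ended in 3 of the 8 fits without 1 array and with a pseudocount of 64. The C1S call at 8 h ended with that pseudocount and with all probe sets averaged. The C1R difference did not pass with a pseudocount of 1 or on the arrays compared alone. Means of C3, C1S and CFB under 16.006 make their values depend on the pseudocount.

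The change from 4 to 24 h without LPS and the LPS change at 8 h, which share no arrays, correlated negatively across 14404 genes, which are not independent (r = -0.23, rho = -0.20). Of the 630 genes that rose without LPS 193 were lower and 21 higher with LPS at 8 h and the rest not called, SLC2A12 (1.41, 0.90 on the high arrays, and -2.97) and B3GALT2 (2.35 and -2.02) among them. Bias with signal is argued against, since r was -0.23 after a trend on mean signal was removed from both changes. Both comparisons hold as many low arrays in either group, so batch shifts cancel. Taking each array's spike-in signal as a covariate (r = -0.22) therefore decides nothing. Nor does r on the high arrays (-0.097), with 1 array for each control time. Chance was not excluded, since 4 of the 35 splits of the 8 arrays at 8 h gave a correlation as strong (highest other 0.28). That LPS may hold back changes of time in culture stays an untested hypothesis.

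The probe set used for SPIDR, a DNA repair gene, changed with LPS by 4.01, 2.47 and 1.89 at 4, 8 and 24 h, close to the 3.95, 2.53 and 2.11 of CEBPD, an inflammatory transcription factor and its neighbour among protein-coding genes, while the other SPIDR probe sets changed by -0.38, 1.24 and -0.33 at 4 h. Deviations from the group means correlated over the 24 arrays at r = 0.78 (permutation p = 0.00517) and rho = 0.60 (permutation p = 0.0157, 100000 permutations, 2-sided), r being 0.60 without the 2 arrays farthest from the median, 0.77 on the 14 high and 0.80 on the 10 low arrays. Reading of CEBPD RNA or joint regulation of neighbours could give this r, and both stay open. The brightest other SPIDR probe set did not rise (-0.38, -0.15, -0.03), while the other CEBPD one did (4.07, 2.42, 1.94). No other relation across samples was computed.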
